A study of Rhodotorula mucilaginosa with 2 samples.

How the data were processed

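RNA was sequenced from cells of the red yeast Rhodotorula mucilaginosa grown in NYDB broth, per the labels' protocols, for 24 h at 28 °C with shaking at 180 rpm. There were 2 libraries. The control library came from a culture without patulin, and the other from a culture given patulin, a mycotoxin made by moulds of apples and other fruit. The labels give the dose as 20 mg/mL and give no replicate cultures. The unit of that dose is in doubt, and nothing in the labels lets it be checked. The text on extraction in the labels speaks of an animal tissue and the submitters' processing notes name the mouse build mm8 and Bowtie 0.12.2. Neither fits a table of yeast transcripts, so they were not used to describe how the values were made.

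Each library had a table of 9201 unigenes, which are transcripts assembled from reads and named by the Trinity assembler's scheme of component and gene number. No genome was used here, so no coordinates are given. Per the file headers the deposited tables hold an expected count, a TPM and an FPKM for each unigene. Expected counts are estimates that share reads between similar transcripts, and 27.3% of them in the control table and 26.5% in the patulin table were not whole. The counter, the assembly and any filter are not given in the sources used here. A further deposited table gave each annotated unigene's best database hit with its score, E-value and percent identity, per the file headers. The highest E-value in it was 9.29e-06. It covered 3625 unigenes, all among the first 4585 in the order of their identifiers, of which 79.1% had a hit. The other 4616 unigenes had no annotation in the table used here, and annotated unigenes held 45.2% of the counts of the control library and 49.8% of those of the patulin library. Gene names below are those of the best hits, mostly proteins of related red yeasts, and are not checked further.

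Expected counts were rounded to whole numbers. The totals were 10568017 for the control library and 8222781 for the patulin library. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3), which gave factors of 1.04 for control and 0.957 for patulin, over unigenes with a mean of at least 10 counts. There were 7232 such unigenes, 3204 of them annotated, and these are called tested unigenes below. The log2 ratio of patulin over control was computed with a prior count of 2 scaled to library size. Its 95% interval is the exact (Clopper-Pearson) conditional binomial interval of the 2 counts. Intervals and floors cover counting error only, because reads copied in PCR are not independent molecules and because nothing measures the spread between cultures.

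With 1 library per group no test between conditions was possible, and no p-value is given. A unigene was called higher or lower by a size rule: a ratio of at least 2-fold, with the 95% interval leaving out equality. It compares these libraries, not the conditions. Where a library had 0 counts, the fold is a bound computed against a floor of 3 counts in that library and is printed as at least that fold. It takes the other count as exact, so it is less cautious than the 95% interval. For TRINITY_DN22_c0_g1, printed as at least 272-fold, the interval reached down to a log2 ratio of 7.79. The design comprised 31 lists of gene families, fixed before the data were examined, of which 30 are defined by words in the hit descriptions and 1 by a best hit outside the fungi. A list's median log2 ratio was given its percentile among the medians of 10000 random lists of tested annotated unigenes, of the same size and matched on 10 bins of mean expression. A list was called apart at a percentile of at most 2.5 or at least 97.5, and needed at least 5 tested members. This describes the libraries and is not a test. Setting members with 0 counts at their floor bound left the median of each of the 31 lists where it was.

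Named unigenes followed a rule fixed before the data were examined. Those eligible had a mean of at least 50 counts, were past the size rule and had a hit with a protein or family name. The rule took the 8 highest and 8 lowest log2 ratios, then the highest and lowest eligible member of each list, or its most abundant member where none was eligible, and the 3 unigenes with most counts in each library. Unigenes chosen after their values were seen are said to be so. Because assembled transcripts of near-identical sequence may share reads, unigenes of 1 Trinity component with the same hit description were also summed into 7611 loci. That step was chosen after seeing the data. Unigenes of one locus are called sisters below.

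The steps were tested on simulated data: Poisson counts for the real unigenes at the real library sizes, with 200 unigenes changed. Simulated unigenes with a mean of at least 10 counts numbered 7232, 197 of them changed and 7035 unchanged. Among these, 91.8% of those changed by 1.2 on the log2 scale and 99% of those changed by 2 were called in the right direction, and 23 of the unchanged ones were called. The intervals held the true ratio for 95.4%. Of 40 lists of 20 random members, 0 were called apart, and 39 were once 0.3 had been added to their log2 ratios. The simulation holds counting error and no spread between cultures.

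Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, total counts, the upper quartile, deposited TPM and FPKM with a pseudocount of 1, prior counts of 0.5 and 8, no count minimum, a mean of at least 100 counts, unigenes of at least 500 bases, folds of 1.5 and 4, no interval, annotated unigenes only, random lists matched on 3 bins of length too or drawn from all tested unigenes, and members with the same description summed. Those added later were the loci, whole Trinity components, fungal best hits only and a wider definition of ribosomal proteins. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.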

Results

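The data were 2 RNA-seq libraries of Rhodotorula mucilaginosa, a red basidiomycete yeast, grown for 24 h without patulin or with patulin at a labelled dose of 20 mg/mL, whose unit is in doubt and was not checked here. The control library held 10568017 expected counts and the patulin library 8222781, over 9201 assembled unigenes. There was 1 library per group, so no value below has a replicate check, and intervals in brackets are 95% intervals of the ratio from counting error alone. The comparison asks how transcript levels differed when patulin was present.

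Oxidoreductases were among the unigenes far higher in the patulin library and among those far lower. An aldo/keto reductase (TRINITY_DN2755_c0_g1), from a family of enzymes that reduce carbonyl groups with NADPH, had 10 counts in the control library and 2849 in the patulin library, a log2 ratio of 8.34 [7.76 to 9.70]. A unigene annotated as an NAD P-binding protein (TRINITY_DN1950_c0_g1) had 169 and 1825 counts, a log2 ratio of 3.90 [3.69 to 4.16]. A unigene whose best hit, at 35.03% identity, was a BAG3-like protein (TRINITY_DN2511_c7_g1) had 102 counts in control and 1435 with patulin, a log2 ratio of 4.27 [4.01 to 4.61]. BAG3 belongs to a family of co-chaperones of Hsp70. In the other direction, a member of the glucose/ribitol dehydrogenase family (TRINITY_DN255_c0_g1) had 620 counts in control and 8 with patulin, a log2 ratio of -5.52 [-7.01 to -4.80]. A diamine N-acetyltransferase (TRINITY_DN2058_c2_g1), an enzyme class that acetylates polyamines, had 1312 and 86 counts, a log2 ratio of -3.42 [-3.78 to -3.13].

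Of 7232 tested unigenes, 376 were higher and 449 lower in the patulin library by the size rule, together 11.4%. Of the tested unigenes, 76.7% had levels within 1.5-fold of each other, and the median log2 ratio was -0.01. Annotated unigenes made up 151 of the higher and 217 of the lower ones. Only the 3625 annotated unigenes could enter a list below, so each list may hold just a part of its family. After sister unigenes had been summed into loci, a step chosen after the data were seen, 200 of 6142 tested loci were higher and 246 lower. Scaling by total counts, which shifted the median of all tested unigenes by -0.12, gave 323 higher and 566 lower.

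**Figure D1:**
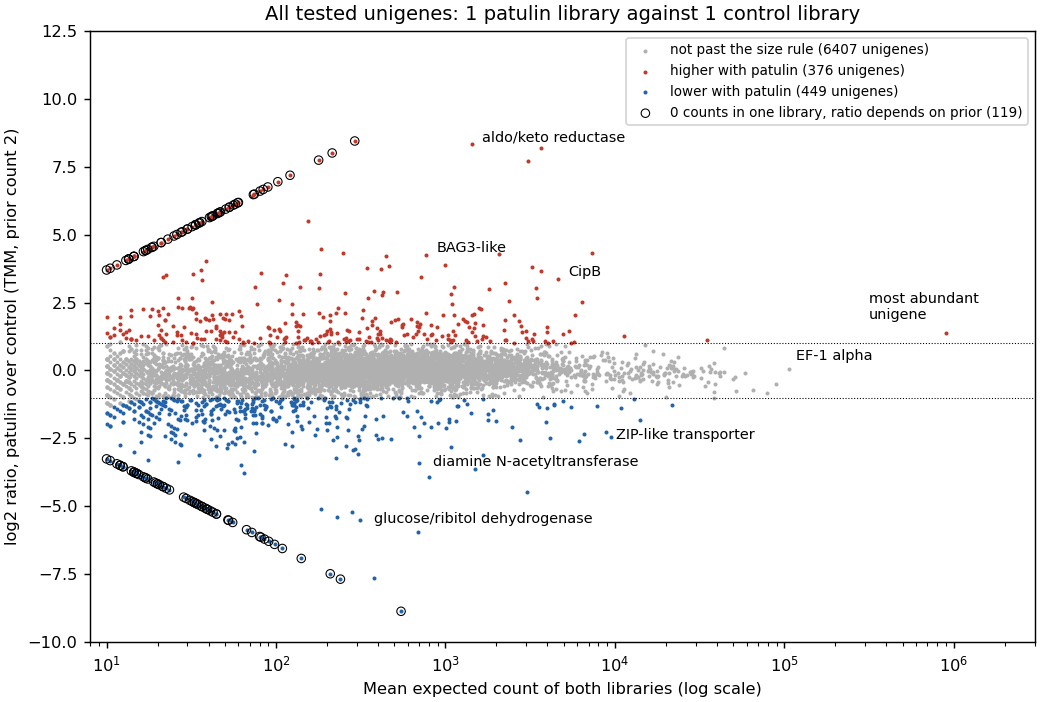
Each point is a tested unigene, with the mean expected count of both libraries on a log axis and the log2 ratio of patulin over control on the vertical axis. Red points are the 376 called higher and blue points the 449 called lower, dotted lines mark 2-fold, and the 119 circled points have 0 counts in one library, so that their ratio depends on the prior count.

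Several of the 16 unigenes that the rule takes for their extreme ratios had no counts in one library and a sister unigene that balanced them. A telomere maintenance protein was split between TRINITY_DN22_c0_g1, with 0 counts in control and 583 with patulin (at least 272-fold higher), and TRINITY_DN22_c0_g2, with 1094 and 0 counts (at least 260-fold lower). Their sum was 1094 in control and 583 with patulin, a log2 ratio of -0.42. The higher unigenes for dolichol kinase (TRINITY_DN1653_c0_g2, 0 and 161 counts), a TAF1 protein kinase (TRINITY_DN2479_c2_g5, 0 and 119), a haloacid dehalogenase-like hydrolase (TRINITY_DN1568_c0_g2, 0 and 106) and a capsular associated protein (TRINITY_DN1619_c0_g2, 0 and 101) were at least 75.3-, 55.6-, 49.5- and 47.2-fold higher with patulin. Their loci had log2 ratios of -0.16, 0.00, 0.39 and -0.26, none past the size rule. The lower unigenes for a RING-type zinc finger protein (TRINITY_DN2391_c1_g2, 181 and 0 counts), the kinase ATG1 (TRINITY_DN2391_c4_g2, 111 and 0) and a cysteine peptidase C50 (TRINITY_DN2444_c0_g2, 105 and 0) were at least 43.0-, 26.4- and 24.96-fold lower. Their loci had log2 ratios of -0.52, 0.07 and -0.19. A mitogen-activated protein kinase kinase unigene (TRINITY_DN2171_c0_g2) had 524 and 47 counts, and its locus a log2 ratio of -0.32. A further unigene, TRINITY_DN116_c0_g1, had 480 counts in control and 0 with patulin (at least 114-fold lower). Its best hit, at 100% identity, was a phage DNA packaging protein that the annotation lists under bacteria.

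Reductases and dehydrogenases that keep their ratio as loci were examined next, and those in this paragraph were chosen after their values were seen unless the lists named them. The zinc-binding oxidoreductases CipB (TRINITY_DN2533_c0_g1) and ToxD (TRINITY_DN2731_c0_g1) had 1086 and 908 counts in control against 8119 and 3856 with patulin, log2 ratios of 3.39 [3.30 to 3.48] and 2.57 [2.47 to 2.68]. A unigene named zinc-binding alcohol in the annotation (TRINITY_DN3278_c0_g1) had 1006 and 5858 counts, a log2 ratio of 3.03 [2.93 to 3.13]. An NADPH2 dehydrogenase (TRINITY_DN1712_c0_g4), of a family that reduces alkenals and enones, had 82 and 431 counts, a log2 ratio of 2.85 [2.54 to 3.24]. It shares a Trinity component with a P450 unigene that was lower, and the component summed to 525 and 556 counts, a log2 ratio of 0.57, so its value is uncertain. Others were lower. An NAD dependent oxidoreductase (TRINITY_DN1170_c0_g1) had 650 and 133 counts, and its locus of 2 unigenes 745 and 142, a log2 ratio of -1.89 [-2.17 to -1.64]. A mitochondrion NAD(P)-binding protein (TRINITY_DN2275_c0_g1) had 198 and 57 counts, a log2 ratio of -1.28 [-1.76 to -0.88], and an electron-transferring-flavoprotein dehydrogenase locus of 3 unigenes had 235 and 75, a log2 ratio of -1.14 [-1.55 to -0.78]. The list of aldo-keto, enone and quinone reductases had 5 tested members, 0 of them lower and 2 higher, TRINITY_DN2755_c0_g1 and TRINITY_DN1739_c0_g2. The words that define the lists do not match NADPH2 dehydrogenase, zinc-binding alcohol, CipB or ToxD, which were higher. Nor do they match the glucose/ribitol dehydrogenase family member (TRINITY_DN255_c0_g1, log2 ratio -5.52) or the NAD dependent oxidoreductase (TRINITY_DN1170_c0_g1), which were lower. All of these are therefore outside this list and the dehydrogenase lists below. The median of the reductase list, 0.18, lay at percentile 85.8, inside the range of random lists, and was 0.83 at percentile 99.75 with no count minimum. In the alcohol and aldehyde dehydrogenase list, 1 of 11 was higher and 2 were lower (of 9 loci, 1 higher and 0 lower), with a median of -0.13, a mean of 0.17 and percentile 37.3. Its lowest eligible member (TRINITY_DN335_c0_g2) is a WD repeat protein with 217 and 31 counts whose locus had a log2 ratio of 0.06. The short-chain dehydrogenases had a median of -0.04 and percentile 50.9, with 1 of 10 lower, TRINITY_DN3363_c0_g1, at 4207 counts in control and 715 with patulin, a log2 ratio of -2.07 [-2.19 to -1.95].

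The list of glutathione synthesis and conjugation had a median log2 ratio above that of random lists, though its summed share of the raw counts was lower. Of 6 tested unigenes, 1 was higher, 0 were lower and 5 did not pass the size rule. The median log2 ratio was 0.47, at percentile 99.6 of random lists. The catalytic subunit of glutamate-cysteine ligase (TRINITY_DN2561_c0_g1), which makes the first step of glutathione synthesis, had 1738 counts in control and 3848 with patulin, a log2 ratio of 1.63 [1.55 to 1.72]. Gamma-glutamyltranspeptidase (TRINITY_DN3353_c0_g1) had a log2 ratio of 0.50 and a glutathione S-transferase (TRINITY_DN2070_c0_g1) one of -0.54, so members lay on both sides of 0. The most abundant member, a glutathione gamma-glutamylcysteinyltransferase (TRINITY_DN1079_c0_g2), had 13210 and 6023 counts, a log2 ratio of -0.65, and its low-count sister (TRINITY_DN1079_c0_g1) one of 0.90, with -0.58 for their locus. The transpeptidase and the gamma-glutamylcysteinyltransferase use glutathione rather than make it, so the list's median does not describe synthesis alone. The list took 0.176% of the raw control total and 0.159% of the raw patulin total, which are not TMM-scaled as the ratios are. TRINITY_DN1079_c0_g2 alone held 13210 of the list's 18635 control counts and 6023 of its 13040 patulin counts, so it dominates these shares.

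Antioxidant and thiol-redox proteins did not stand apart over all tested unigenes, with 2 of 13 higher, 3 lower, a median of 0.17 and percentile 94.4. All 3 lower ones were fragments of catalase A, which breaks down hydrogen peroxide. The lowest (TRINITY_DN1674_c0_g4) had 118 and 12 counts, and the 4 sister unigenes together had 268 and 62, a log2 ratio of -1.60. The higher ones were a glutaredoxin (TRINITY_DN2186_c1_g1), which reduces disulfides with glutathione, at 448 and 1737 counts, a log2 ratio of 2.44 [2.29 to 2.60], and peroxiredoxin 5 (TRINITY_DN2062_c2_g1) at 1946 and 3677, a log2 ratio of 1.40 [1.33 to 1.49]. With sister unigenes summed the list's median was 0.39, at percentile 99.8, and with a mean of at least 100 counts it was 0.62, at percentile 100. Genes of sulfate assimilation and cysteine synthesis gave a like picture, with 2 of 11 unigenes higher, 1 lower, a median of 0.13, a mean of -0.06 and percentile 88.8. With sisters summed the median was 0.48, at percentile 99.8, and with a mean of at least 100 counts it was also 0.48, at percentile 99.2. Cystathionine gamma-lyase (TRINITY_DN2844_c0_g1), which makes cysteine, had 739 and 1865 counts, a log2 ratio of 1.82 [1.70 to 1.95]. Of this list's members, the lower one was 1 of 4 fragments of a sulfate permease, with 39 and 0 counts, whose locus had 215 and 95, a log2 ratio of -0.68. The second higher one (TRINITY_DN175_c0_g1, 11 and 19 counts) had a locus ratio of 0.83, so 1 of 7 loci was higher and 0 lower.

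**Figure D2:**
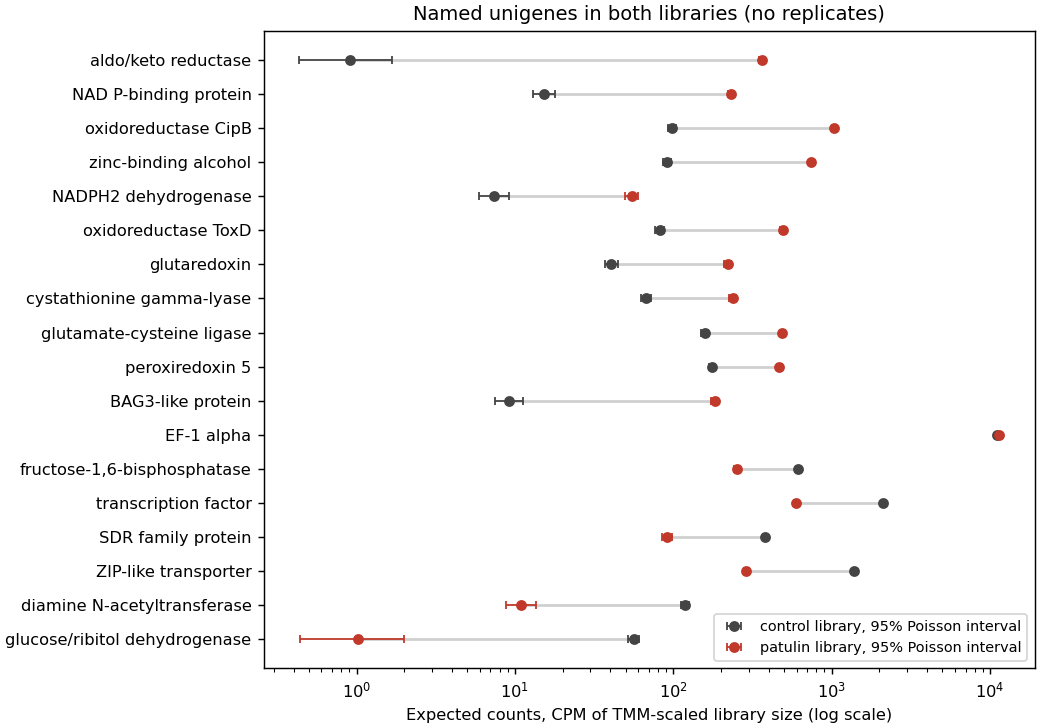
Expected counts as CPM of the TMM-scaled library size, on a log axis, for 18 named unigenes in the control library (grey) and the patulin library (red), with 95% Poisson intervals that cover counting error only. The aldo/keto reductase and the glucose/ribitol dehydrogenase lie at opposite ends, with log2 ratios of 8.34 and -5.52, and elongation factor EF-1 alpha, at 0.05, lies nearly on itself.

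Of 4 lists of protein production, those of ribosome biogenesis and of translation lay above random lists, by small amounts. Of 20 tested unigenes of ribosome biogenesis and rRNA processing, 18 had a positive log2 ratio, although 2 were higher by the size rule and 0 lower. The median was 0.22, at percentile 99.6. The highest eligible member was a ribosome biogenesis ATPase (TRINITY_DN1882_c0_g2) with 31 and 93 counts, whose locus had a log2 ratio of 0.30. The other higher member was Sqt1 (TRINITY_DN2796_c0_g1), a factor for loading a ribosomal protein of the large subunit, at 758 and 1325 counts, a log2 ratio of 1.29 [1.16 to 1.42]. Translation factors and aminoacyl-tRNA synthetases had a median of 0.17, at percentile 99.6, with 24 of 36 above 0, 1 higher and 4 lower, and scaling by total counts made the median 0.0477. Their mean was -0.06, since the lower members were low-count fragments with more abundant sisters, such as eIF-4e (TRINITY_DN1117_c0_g1, 71 and 11 counts), whose locus had a log2 ratio of 0.45. Aspartyl-tRNA synthetase (TRINITY_DN3330_c0_g1) had 948 and 2006 counts, a log2 ratio of 1.57 [1.46 to 1.68]. Cytosolic ribosomal proteins did not stand apart, with 2 of 26 higher, 1 lower, a median of -0.06, a mean of 0.05 and percentile 29.1. The higher ones were l10 (TRINITY_DN1069_c0_g1), at 27251 and 42266 counts, and l37 (TRINITY_DN2389_c0_g3), at 727 and 6554 counts, a log2 ratio of 3.66 [3.55 to 3.77]. The l37 unigene shares a Trinity component with ubiquitin fusion transcripts, so its reads may be divided among different genes and its value is uncertain. That component had 54038 and 40752 counts, a log2 ratio of 0.08. The lower one was l11 (TRINITY_DN3398_c0_g1), at 2952 and 591 counts, whose locus had a log2 ratio of -0.11. The mitochondrial ribosomal list, with 1 of 9 lower, a median of 0.00, a mean of -0.11 and percentile 63.4, also took in 6 unigenes with cytosolic names such as S27Ae and L40e. Its lower member was Rsm25 (TRINITY_DN1582_c0_g1), at 91 and 29 counts, a log2 ratio of -1.12 that lay inside 2-fold in TPM (-0.90) and FPKM (-0.93) and turned to 0.23 with its component summed (923 and 774 counts).

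Cytochrome P450 and other monooxygenases had a median log2 ratio below that of random lists. Of 13 tested unigenes, 4 were lower, 0 higher and 9 did not pass the size rule, and the median was -0.46, at percentile 0.14. Of 10 loci 3 were lower, since the lower unigene TRINITY_DN1989_c0_g1 (225 and 78 counts) had a locus ratio of -0.35. The lowest was a flavin-containing monooxygenase (TRINITY_DN1030_c0_g1), with 137 counts in control and 35 with patulin, a log2 ratio of -1.44 [-2.06 to -0.94]. Unigenes resembling P450 families 4 (TRINITY_DN1712_c0_g1) and 3 (TRINITY_DN2054_c0_g1) had 428 and 205 counts in control and 114 and 57 with patulin, log2 ratios of -1.41 and -1.33. The former shares its component with the NADPH2 dehydrogenase above, and the lowest member shares one with farnesyl diphosphate synthase (973 and 757 counts together), so both values are uncertain. The list also holds COQ6 and COQ7, enzymes of ubiquinone synthesis, with log2 ratios of -0.05 and -0.17. The cell wall list had a median of -0.20 at percentile 0.83, with 10 of 36 above 0, 1 lower and 0 higher. The lower one (TRINITY_DN1718_c0_g3, 194 and 56 counts, locus log2 ratio -0.94) is a glycogen debranching enzyme, which acts on a storage polysaccharide and not on the wall. A chitin synthase (TRINITY_DN2368_c0_g1) had 2571 and 1278 counts, a log2 ratio of -0.52, without passing the size rule, and the 1,3-beta-glucan synthase (TRINITY_DN2817_c0_g1) had a log2 ratio of -0.11. With sisters summed this list lay at percentile 4.33 and no longer stood apart. The 5 lists that stood apart compare with 1.4 of 28 expected if members were unrelated beyond their expression level. Members of a family may vary together, so this comparison is not a test.

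**Figure D3:**
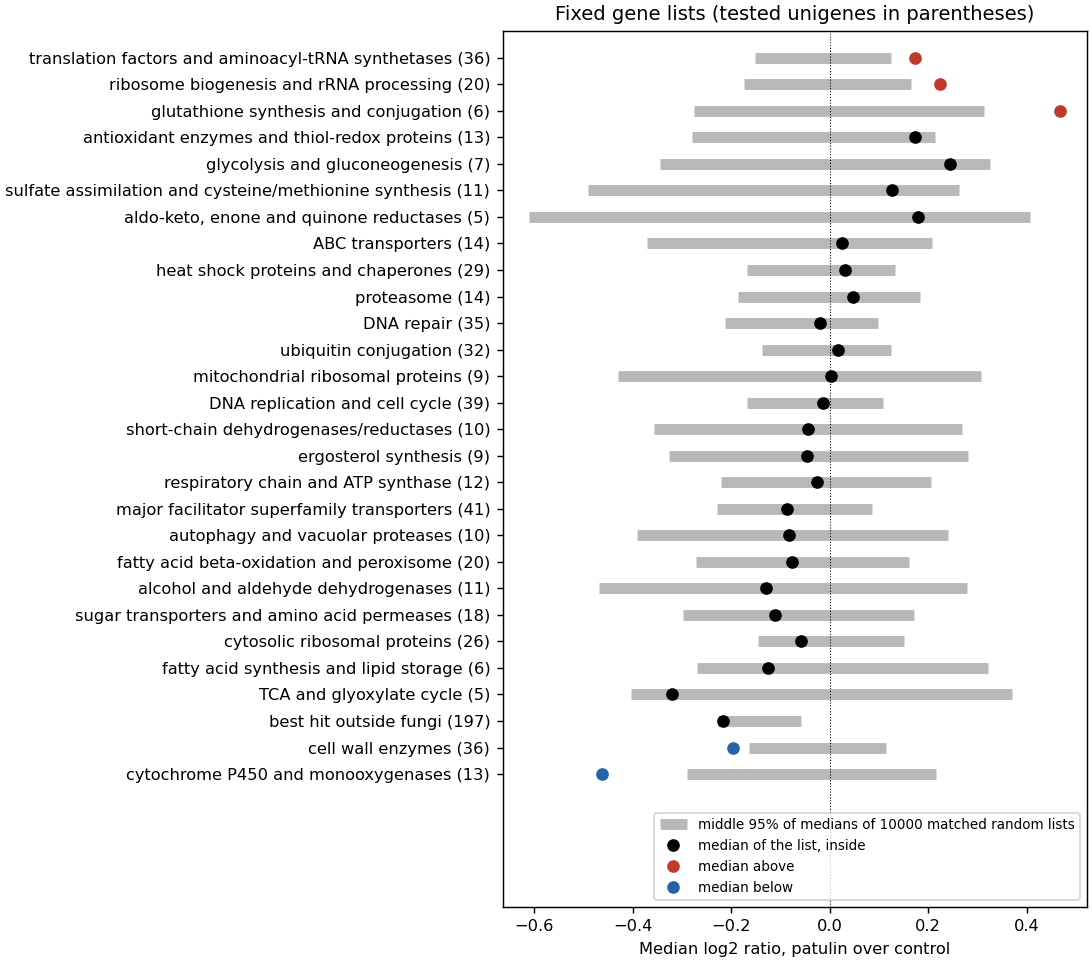
Points are the median log2 ratios of patulin over control of the 28 lists with at least 5 tested unigenes, and grey bars hold the middle 95% of medians of 10000 matched random lists. Red points mark the 3 lists above their bar and blue points the 2 below it, with medians of 0.47 for glutathione and -0.46 for monooxygenases farthest out.

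Transporters were divided in direction. The major facilitator superfamily had 5 of 41 unigenes higher and 7 lower, a median of -0.09 and percentile 40.6. Of its 33 loci, 4 were higher and 3 lower, because 4 of the lower unigenes were low-count fragments whose loci did not pass the rule. Unigenes annotated as polyamine transporters were found at both ends, TRINITY_DN1919_c0_g1 with 27 and 192 counts, a log2 ratio of 3.21 [2.73 to 3.96] (200 and 543 counts for its locus, a log2 ratio of 1.92), and TRINITY_DN2323_c0_g1 with 323 and 69, a log2 ratio of -1.72 [-2.14 to -1.36]. Sugar transporters and amino acid permeases had 1 of 18 higher, an amino acid transporter (TRINITY_DN1846_c0_g1, 67 and 140 counts, inside the size rule at 0.76 with its component summed), and 1 lower, a monosaccharide transporter (TRINITY_DN23_c0_g1, 429 and 142 counts), with a median of -0.11, a mean of 0.01 and percentile 30.96. ABC transporters had 1 of 14 higher and 1 lower, which were sisters of 1 locus (TRINITY_DN2329_c0_g2 with 82 and 0 counts and TRINITY_DN2329_c0_g4 with 4 and 73), a median of 0.03 and percentile 75.2. Their most abundant member, the mitochondrial transporter ATM (TRINITY_DN2002_c0_g1), had 3686 and 2095 counts, a log2 ratio of -0.33.

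Protein folding and turnover lists did not stand apart. Heat shock proteins and chaperones had 2 of 29 higher and 1 lower, a median of 0.03 and percentile 74.3. The higher ones were an HSP20-like protein (TRINITY_DN2279_c1_g1), at 253 and 540 counts and a log2 ratio of 1.57 [1.36 to 1.80], and an Hsp70 family member (TRINITY_DN2498_c2_g1), at 2401 and 4295 counts and a log2 ratio of 1.33. The most abundant Hsp70 (TRINITY_DN2498_c0_g1) had 70177 and 46722 counts, a log2 ratio of -0.10. The lower DnaJ unigene (TRINITY_DN1032_c0_g2, 152 and 49 counts) had a locus ratio of 0.03. The proteasome list had 1 of 14 lower, subunit alpha 5 (TRINITY_DN1799_c0_g1, 616 and 215 counts, locus log2 ratio 0.32), a median of 0.05 and percentile 69.7. Ubiquitin conjugation had 0 of 32 past the size rule, a median of 0.02, a mean of -0.02 and percentile 64.2, and its most abundant member, polyubiquitin (TRINITY_DN2389_c0_g8), had 28231 and 13350 counts, a log2 ratio of -0.59 that became 0.03 in TPM. The autophagy list had 0 of 10 past the rule, a median of -0.08 and percentile 40.5, with autophagy-related protein 11 (TRINITY_DN1814_c0_g1) at 1498 and 882 counts.

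DNA repair had 2 of 35 unigenes lower and 0 higher, with 0 of 29 loci past the rule, a median of -0.02 and percentile 66.9. Its lowest eligible member, a DNA ligase (TRINITY_DN1_c0_g1), had 188 and 66 counts, a log2 ratio of -1.004, and lay inside 2-fold under DESeq2 size factors and as a locus. DNA replication and cell cycle had 2 of 39 higher and 0 lower, with 0 of 33 loci past the rule, a median of -0.01, a mean of 0.19 and percentile 60.6, and its most abundant member, MCM6 (TRINITY_DN2286_c0_g4), had 4118 and 2663 counts.

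In central metabolism, fructose-1,6-bisphosphatase (TRINITY_DN1039_c0_g1), an enzyme of gluconeogenesis, had 6737 counts in control and 1988 with patulin, a log2 ratio of -1.27 [-1.346 to -1.201]. Its Trinity component, with a further locus, had 7722 and 2976 counts, a log2 ratio of -0.89 that lies inside the size rule. The enzyme was the 1 lower member of 7 in the glycolysis list, whose median was 0.24, whose mean was -0.01 and whose percentile was 94.2. That median fell to 0.05 with a mean of at least 100 counts (percentile 62.05), fungal best hits only (63.67) and the same description summed (71.81). The TCA list had 0 of 5 past the rule, a median of -0.32 and percentile 4.51, with citrate synthase (TRINITY_DN3304_c0_g1) at 46209 and 24636 counts, a log2 ratio of -0.42. It also took in beta-isopropylmalate dehydrogenase, an enzyme of leucine synthesis. The respiratory chain list had 0 of 12 past the rule, a median of -0.03 and percentile 43.3. Its most abundant member, subunit 4 of NADH dehydrogenase 1 alpha (TRINITY_DN3312_c0_g1), had 29540 and 10632 counts, a log2 ratio of -0.99, which passed 2-fold when scaled by total counts, at -1.11. Ergosterol synthesis had 0 of 9 past the rule, a median of -0.05, a mean of 0.16 and percentile 46.3. Its most abundant entry was an oxysterol-binding protein (TRINITY_DN2434_c3_g1), which binds sterols and does not make them, with a log2 ratio of -0.16. Fatty acid beta-oxidation had 1 of 20 lower, with 0 of 16 loci past the rule, a median of -0.08 and percentile 40.4, with an acyl-CoA dehydrogenase (TRINITY_DN216_c0_g1) at -0.38. Fatty acid synthesis had 0 of 6 past the rule, a median of -0.13 and percentile 15.1, with fatty acid synthase subunit alpha (TRINITY_DN2540_c1_g2) at -0.17, which became 0.15 in TPM.

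For 3 lists fewer than 5 members were tested and no percentile was computed, and none of their members passed the size rule. Glucose-6-phosphate dehydrogenase (TRINITY_DN3331_c0_g1), which supplies NADPH and was 1 of 2 pentose phosphate members, had 6319 and 6484 counts, a log2 ratio of 0.52 [0.47 to 0.58], and that list's median was 0.22. The 4 carotenoid and prenyl members had a median of 0.25, with farnesyl diphosphate synthase (TRINITY_DN1030_c0_g2) at 836 and 722 counts, a log2 ratio of 0.28, and the 4 iron and copper uptake members a median of -0.22, with a ferric reductase (TRINITY_DN1089_c0_g2) at 9701 and 6292, a log2 ratio of -0.14.

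The most abundant unigene in both libraries was TRINITY_DN2501_c0_g1, of 6334 bases, whose best hit was a hypothetical protein of a ciliate at 57.6% identity. It took 5.91% of the raw control counts (95% exact binomial interval 5.89 to 5.92%) and 14.3% of the raw patulin counts (14.25 to 14.3%). Its log2 ratio, which is TMM-scaled as these shares are not, was 1.40. No sequence was used here to check whether it derives from ribosomal RNA, so what its share measures is open. Elongation factor EF-1 alpha (TRINITY_DN3279_c0_g1) followed with 121946 and 89821 counts, a log2 ratio of 0.05, and then an unannotated unigene (TRINITY_DN6062_c1_g1) with 118490 and 59136 counts, a log2 ratio of -0.51. The 197 tested unigenes with a best hit outside the fungi had a median of -0.22, at percentile 4.08, with 6 higher and 28 lower.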

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

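Alternatives that summed sister unigenes or whole Trinity components, or that kept fungal hits only or widened the ribosomal list, were chosen after the data were seen. Of 416 alternative values of the 28 lists with a percentile, 403 kept their side of the limits, 10 came to stand apart, 2 no longer did, 1 that was not apart moved by more than the random range allows and 0 reversed. Keeping a side says nothing of the size of a median. DESeq2 size factors, total counts and the upper quartile move a list and its random lists together, so they could hardly change a percentile. The glutathione list lay at 99.58 under each of them, so these settings do not check whether a list stands apart. A setting that left a list under 5 members gave no value for it. Whole Trinity components were summed for the counts and for named unigenes, but not for any list. The doubt that components raise about TRINITY_DN1030_c0_g1 and TRINITY_DN1712_c0_g1 was therefore not tested on the monooxygenase list. The glutathione, ribosome biogenesis, translation and monooxygenase lists stood apart in each of 15 alternatives, at percentiles of 98.3 to 99.6, 99.03 to 99.72, 99 to 99.99 and 0.04 to 0.54. Their medians ranged over 0.34 to 0.48, 0.0995 to 0.24, 0.0477 to 0.25 and -0.59 to -0.34, and the translation median was lowest with total counts (0.0477) and FPKM (0.0481). The cell wall list no longer stood apart with sister unigenes summed (median -0.15) or the same description summed (-0.14). The antioxidant and sulfate lists stood apart only with a mean of at least 100 counts (0.62 and 0.48), with the same description summed (0.39 and 0.48) and with sister unigenes summed (0.39 and 0.48), settings that drop or merge low-count fragments. The reductase list stood apart with no count minimum (0.83), as a further member at low counts entered. Best hits outside fungi stood apart with a mean of at least 100 counts (-0.18), with random lists from all tested unigenes (-0.22) and with the same description summed (-0.24). The sugar transporter list moved to 0.21 with a mean of at least 100 counts, and the cause was not tested.

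The counts of 376 higher and 449 lower unigenes became 205 and 159 with a mean of at least 100 counts, 714 and 815 at 1.5-fold, 147 and 158 at 4-fold, 151 and 217 among annotated unigenes only, 200 and 246 with sister unigenes summed and 177 and 210 with Trinity components summed. These settings test fewer units or another fold. The other 20 values stayed within 1.5 times. Total counts and FPKM shifted the median of all tested unigenes by -0.12.

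Of 82 named unigenes, 76 kept their side of the size rule under the scalings, priors and units, those not past it also staying inside their interval or within 0.25, and 59 did so with sister unigenes summed too. For the 11 with 0 counts in one library the size of the ratio was not kept. That of TRINITY_DN1653_c0_g2 was 8.60 and 4.65 with prior counts of 0.5 and 8 and 2.90 in FPKM, against 6.61. Summing turned the sign of 7 called unigenes, TRINITY_DN22_c0_g1 (-0.42), TRINITY_DN1653_c0_g2 (-0.16), TRINITY_DN1619_c0_g2 (-0.26), TRINITY_DN2391_c4_g2 (0.066), TRINITY_DN335_c0_g2 (0.060), TRINITY_DN1032_c0_g2 (0.032) and TRINITY_DN1799_c0_g1 (0.32), because sister counts outweighed theirs. Some named unigenes past the size rule share a Trinity component with another locus and lay inside the rule when the whole component was summed, among them TRINITY_DN2389_c0_g3 (0.081), TRINITY_DN1712_c0_g4 (0.57), TRINITY_DN1739_c0_g2 (0.50), TRINITY_DN1030_c0_g1 (0.13), TRINITY_DN1582_c0_g1 (0.23), TRINITY_DN1846_c0_g1 (0.76), TRINITY_DN3317_c0_g2 (-0.15), TRINITY_DN1039_c0_g1 (-0.89) and TRINITY_DN2447_c3_g1 (-0.98). Such a sum mixes loci of different descriptions, so it leaves a value in doubt and does not replace it. No paired analysis was possible because each group has 1 library. Depth limits unigenes near the minimum of 10 counts most, and no alternative replaces the missing replicates.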

Other observations

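The tests of explanations in this part, and the unigenes singled out in it, were all chosen after the results were seen. Loci with large ratios included several groups outside the lists. An acid phosphatase (TRINITY_DN3318_c0_g1), of a class that releases phosphate from organic compounds, had 1280 counts in control and 3780 with patulin, a log2 ratio of 2.05 [1.96 to 2.14], and a second one (TRINITY_DN1946_c0_g2) had 137 and 282, a log2 ratio of 1.51. Peptide-methionine (S)-S-oxide reductase (TRINITY_DN3317_c0_g2), which repairs oxidised methionine, had 71 and 219 counts, a log2 ratio of 2.08 [1.72 to 2.52], but its Trinity component had 1216 and 783, a log2 ratio of -0.15, so its value is uncertain. Some list members had large ratios as well. An aryl-alcohol dehydrogenase locus of 3 unigenes (TRINITY_DN2319_c0_g2 the largest) had 4 and 97 counts, a log2 ratio of 4.45. A further 3 transporters of the major facilitator superfamily (TRINITY_DN2524_c0_g1, TRINITY_DN2371_c11_g1 and TRINITY_DN2836_c0_g1) had log2 ratios of 1.94, 1.80 and 1.73.

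Among loci lower with patulin, a zip-like iron-zinc transporter (TRINITY_DN1742_c0_g1) had 15358 counts in control and 2282 with patulin, a log2 ratio of -2.26 [-2.33 to -2.20]. Unigenes annotated as a transcription factor (TRINITY_DN3327_c0_g1), a C6 transcription factor (TRINITY_DN3319_c0_g1), a C2H2-like zinc finger protein (TRINITY_DN2447_c3_g1) and WetA (TRINITY_DN2623_c0_g1), a regulator of spore maturation in moulds, had log2 ratios of -1.82, -1.87, -2.11 and -1.86, of which the C2H2-like one became -0.98, inside the size rule, with its component summed. The hits for the C2H2-like protein and WetA had only 28.76% and 26.46% identity. Among unigenes without annotation, TRINITY_DN5397_c1_g1 had 32 and 7273 counts and TRINITY_DN3966_c0_g1 had 38 and 6072, log2 ratios of 8.21 and 7.72, while TRINITY_DN3503_c0_g1 had 2810 and 159, a log2 ratio of -3.64.

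Of the called unigenes, 119 had 0 counts in one library, 58 in control and 61 with patulin, and 115 of them shared a Trinity component with other unigenes. Reads shared between near-identical unigenes are a candidate explanation: of 112 with a sister of the same description, 8.0% belonged to a locus that was still past the size rule. Adding a sister's counts would bring a locus inside the rule under different strains or the loss of an allele too. The 8.0% therefore does not tell shared reads apart from those. A second strain in 1 of the libraries would put the zeros in the same library, whereas 51.3% lay in the commoner one. Cultures of 2 different haploid strains stay open. They would leave sisters at 0 in opposite libraries, as in 15 of the 100 loci, and although 91.0% of the loci had a sister above 3 counts in both libraries, expected counts that divide shared reads could put counts in both. Loss of an allele in a culture was not tested and stays open.

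The 8 oxidoreductase unigenes singled out as higher with patulin (aldo/keto reductases, NAD P-binding proteins, CipB, ToxD, zinc-binding alcohol and NADPH2 dehydrogenase) had 3532 counts in control and 23718 with patulin, with log2 ratios of 1.58 to 8.34. With whole components summed, an aldo-keto reductase (TRINITY_DN1739_c0_g2, 0.50) and the NADPH2 dehydrogenase (0.57) lay inside the size rule. They were picked for being higher. Among the 44 higher and 33 lower loci with a mean of at least 50 counts and a protein name, 9 higher and 5 lower ones had a name that speaks of a reductase, a dehydrogenase, NAD or a zinc-binding alcohol enzyme. These counts depend on that wording. It leaves out other oxidoreductase loci, such as catalase A and P450 among the lower and glutaredoxin and peroxiredoxin 5 among the higher. An effect of patulin cannot be told apart from variation between cultures unrelated to patulin, because there was 1 library per group.

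Some unigenes matched other organisms. A set of 8 unigenes with hits of at least 90% identity to vertebrate skeletal muscle proteins totalled 240 counts in the control library and 234 in the patulin library, 22.7 and 28.5 CPM of the raw totals. The unigene with the phage packaging protein hit was at 45.4 CPM in control and 0 of 8222781 counts with patulin, which allows up to 0.365 CPM.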
